A study of Mus musculus with 4 samples.

How the data were processed

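Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where a Flag-tagged form of Sp5 sat on the genome of differentiating mouse embryonic stem cells. Sp5 is a zinc-finger transcription factor of the SP/KLF family and a transcriptional target of Wnt/β-catenin signalling. The cells were A2Lox.cre embryonic stem cells, a line built so that a chosen cDNA can be placed under doxycycline control. Per the labels' protocols, the cells were grown as embryoid bodies, floating aggregates in which stem cells begin to differentiate. Doxycycline was added on day 2 for 24 h and the cells were fixed with formaldehyde on day 3. Chromatin was sheared to about 100 to 300 bp. The M2 antibody against the Flag tag was used at 4 µg per immunoprecipitation, and the libraries were made with the TruSeq ChIP protocol. The 4 libraries formed 2 groups of 2, Flag-Sp5 ChIP and input chromatin without antibody. The treatment label of all 4 libraries gives doxycycline as the inducer of Flag-Sp5, while the titles of the inputs do not name Sp5. No Flag immunoprecipitation from cells without Flag-Sp5 or without doxycycline was among the libraries. Background of the antibody can therefore not be told apart from binding of Flag-Sp5. The labels do not say whether libraries of a group came from separate cultures.

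The data analysed were a single peak list for the whole series with 3 columns, the chromosome, start and end of each peak, as the authors deposited it. Per the submitters' processing notes, the build was mm9 and the tools named were Bowtie, Picard, MACS2 and HOMER, without versions, roles or order. The peak-calling threshold, any removal of repeat regions, and the way the libraries of a group were combined are not given in the sources used here. The list carries no score, summit, height, p-value or read count, and no value for any single library. The depth of the libraries is therefore unknown, no spread between replicates can be given for any value, and no test of ChIP against input was possible. A position enters such a list only if it passed a threshold, so a stretch without peaks is not a measurement of zero binding. The coordinates were checked and no peaks overlapped. On 7 of 20 chromosomes the last peak ended beyond the last gene of the GRCm38.p6 gene table, which alone does not settle the build; mm9 was taken from the submitters' processing notes.

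No mm9 genome or annotation was used here, and coordinates of another build were not mixed in. For this reason the planned tests of promoter-proximal shares, of fixed gene lists and of sequence motifs were not run, and no peak was assigned to a gene. The planned test of peak score by class was not run because the list has no score. The rule for what to name, set before the data were examined, was in this case the 10 widest peaks and the 3 regions with most peaks within 100 kb. Ties for the third place were all kept, which gave 5 regions. The alternatives tried were merging of peaks less than 500 bp apart, peaks wider than the median only, other distances, other random placements and the omission of single chromosomes, and the closing section gives their effect. The 5 Mb blocks were added after seeing the data.

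Coordinates are printed 1-based on mm9. Peak spacing was measured between midpoints. The number of peaks with another midpoint within 10 kb was compared with 1000 uniform placements of the same number of peaks between the first and last peak of each chromosome, and with 1000 lists in which each peak was moved by a random offset of up to 1 Mb, reflected at the ends. These permutation tests were one-sided and their smallest possible p is 0.001. The densest 100 kb window was tested against the same placements, of which the moved lists were added for it after seeing the data. Peaks per chromosome were divided by the span from the first to the last peak, because chromosome lengths were not taken from another source. They were compared with 100000 random allocations of the peaks in proportion to span, a permutation test whose smallest possible p is 1e-05. Because neighbouring peaks are not independent, X was also compared with the autosomes over 5 Mb blocks by a two-sided permutation test with 100000 resamples, and the autosomes with each other by permuting their block counts. Median widths were compared by two-sided permutation tests with 9999 resamples, which treat the peaks as independent. Exact Poisson intervals for densities and Wilson intervals for shares are at 95% and cover counting error of peaks only, not differences between libraries.

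The procedures were tested on simulated lists of 9428 peaks. The spacing test called 1 of 20 unclustered lists and 20 of 20 lists with 200 planted close pairs at p below 0.05. The chromosome test called 0 of 20 even lists and 20 of 20 lists in which the X density was lowered by a factor of 2. A planted region of 12 peaks came out first in 20 of 20 lists. Apart from what was planted, these lists were drawn independently and without the broad density differences of the real list. They therefore give no error rates for lists whose peaks cluster. First place for the planted region was all but certain, since uniform placement gave at most 8 peaks in 100 kb. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.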

Results

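The peak list held 9428 Flag-Sp5 peaks in day 3 embryoid bodies, spread over all 19 autosomes and chromosome X. The autosomes carried 9265 peaks and X carried 163, and no peak was listed on Y. The peaks together covered 2.08 Mb. They came from 2 Flag ChIP and 2 input libraries that the list does not separate, so no value has a replicate error. The question behind the study, as its title and design state it, was where Sp5 binds in differentiating embryonic stem cells. The list concerns the tagged, doxycycline-induced protein, and binding of the cells' own Sp5 was not measured.

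The called peaks were narrow. Their widths are those of the listed intervals and do not measure the extent of binding. Peak width had a median of 195 bp, with the central 50% of peaks between 161 and 250 bp and a mean of 220.5 ± 86.4 bp (SD over 9428 peaks). A width between 100 and 300 bp, the sheared fragment size that the labels give, was found for 8128 peaks (86.2%, 95% Wilson interval 85.5 to 86.9%). The smallest width, 141 bp, was shared by 677 peaks (7.18%, interval 6.68 to 7.72%), while the next most common width, 150 bp, was shared by 113. Only 132 peaks (1.40%, interval 1.18 to 1.66%) exceeded 500 bp.

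The widest peak lay on chromosome 9 from 51842935 to 51844341 and measured 1407 bp. The next widest, both on chromosome 17, ran from 36002645 to 36003735 (1091 bp) and from 27692050 to 27693067 (1018 bp). These were the 3 peaks above 1000 bp. Chromosome 18 held the following pair, at 36047350 to 36048245 (896 bp) and 83712962 to 83713787 (826 bp). Then came peaks on chromosome 7 from 91754310 to 91755123 (814 bp), on chromosome 5 from 25415158 to 25415942 (785 bp) and on chromosome 2 from 32986232 to 32987001 (770 bp). The last of the 10 widest were on chromosome 3 from 96500658 to 96501412 and on chromosome 4 from 140847308 to 140848062, each 755 bp wide. The peaks on chromosomes 2 and 3 had another peak midpoint within 0.714 and 0.579 kb, whereas the widest peak of all stood 270 kb from its nearest neighbour. The gene context of these positions was not analysed here.

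**Figure D1:**
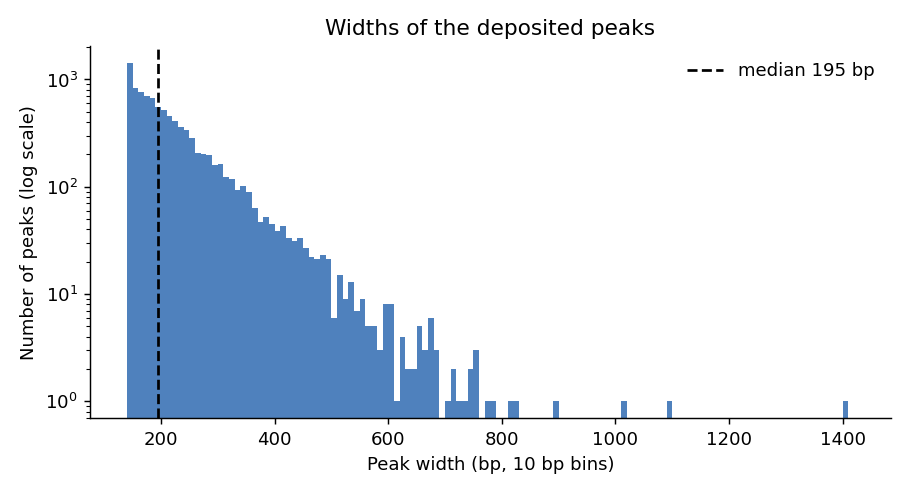
Histogram of the widths of the 9428 peaks in 10 bp bins, with the number of peaks on a log scale and the median of 195 bp as a dashed line. Counts fall from the smallest width of 141 bp, and 3 peaks lie above 1000 bp.

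Peak density differed between chromosomes, and X had the lowest. X carried 1.01 peaks per Mb of span (95% Poisson interval 0.864 to 1.18), against 3.86 per Mb over all autosomes, a ratio of 0.263. Among autosomes the density ran from 2.79 per Mb on chromosome 3 (interval 2.54 to 3.07) to 5.76 on chromosome 11 (interval 5.34 to 6.21), a 2.06-fold range. Chromosomes 5 and 17 followed chromosome 11 with 4.95 and 4.76 peaks per Mb, and chromosomes 1 and 12 were near the low end with 2.89 and 3.03. By span, X would have received 591 of the peaks, and it received 163.

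The differences exceeded the counting error of independent peaks. The chi-square per degree of freedom was 37.4 over all 20 chromosomes, and at most 3.07 in random allocations (permutation test, p = 1e-05, the smallest possible). It was 20.1 over the 19 autosomes alone, where random allocations reached 3.51 (permutation test, p = 1e-05, the smallest possible). Peaks are not independent, and with counts per 5 Mb block permuted across the autosomes the value was 19.4 against a mean of 9.76 and a maximum of 31.1 (permutation test with 100000 resamples, p = 0.0067). Over 5 Mb blocks, X held 5.03 ± 4.20 peaks per block (SD over 32 blocks) and the autosomes 19.1 ± 13.7 (SD over 472 blocks; two-sided permutation test, p = 1e-05, the smallest possible). Blocks of a chromosome are not independent of each other either. With chromosomes as the units, X ranked lowest of 20, for which the exact one-sided rank p is 0.05, the smallest that 20 chromosomes allow. Copy number of X in these cells and the share of each chromosome to which reads can be mapped were not measured in the list.

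**Figure D2:**
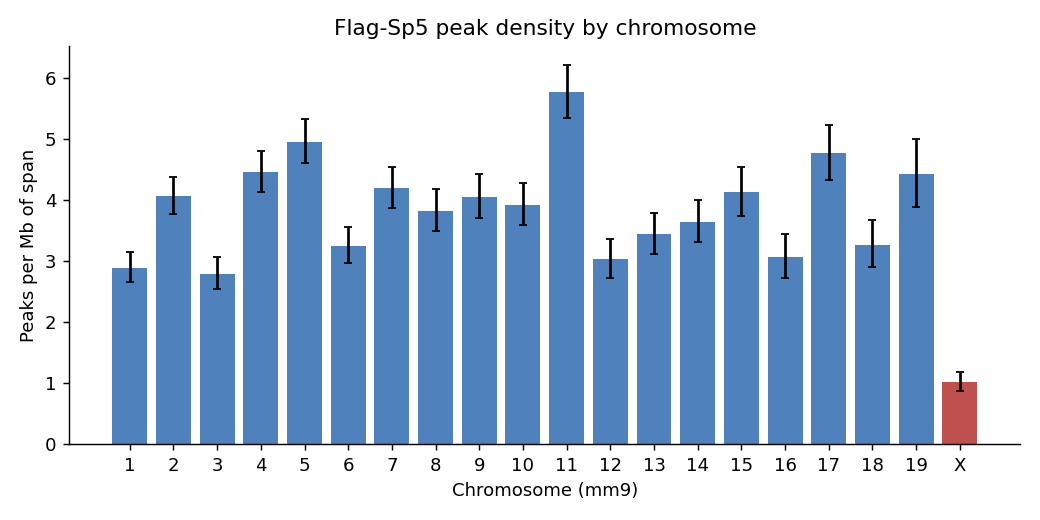
Peaks per Mb of span (first to last peak) on each mm9 chromosome, with 95% exact Poisson intervals as error bars and X in red. X stands at 1.01 per Mb, below every autosome, and chromosome 11 is highest at 5.76.

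Density also varied along chromosomes. The distal part of chromosome 5 held the densest 5 Mb block, from 133283660 to 138283659, with 114 peaks, and the adjoining block up to 143283659 held 71. Chromosome 11 had blocks of 73 peaks from 113024088 to 118024087 and 65 peaks from 98024088 to 103024087, and chromosome 10 had 68 peaks from 78515508 to 83515507. The median block held 15 peaks and no block was empty. These 5 blocks were chosen after their values were seen. The variance of peaks per block was 10.3 times the mean, against 2.36 times on average and at most 2.58 times under uniform placement within chromosomes (permutation test, p = 0.001, the smallest possible).

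**Figure D3:**
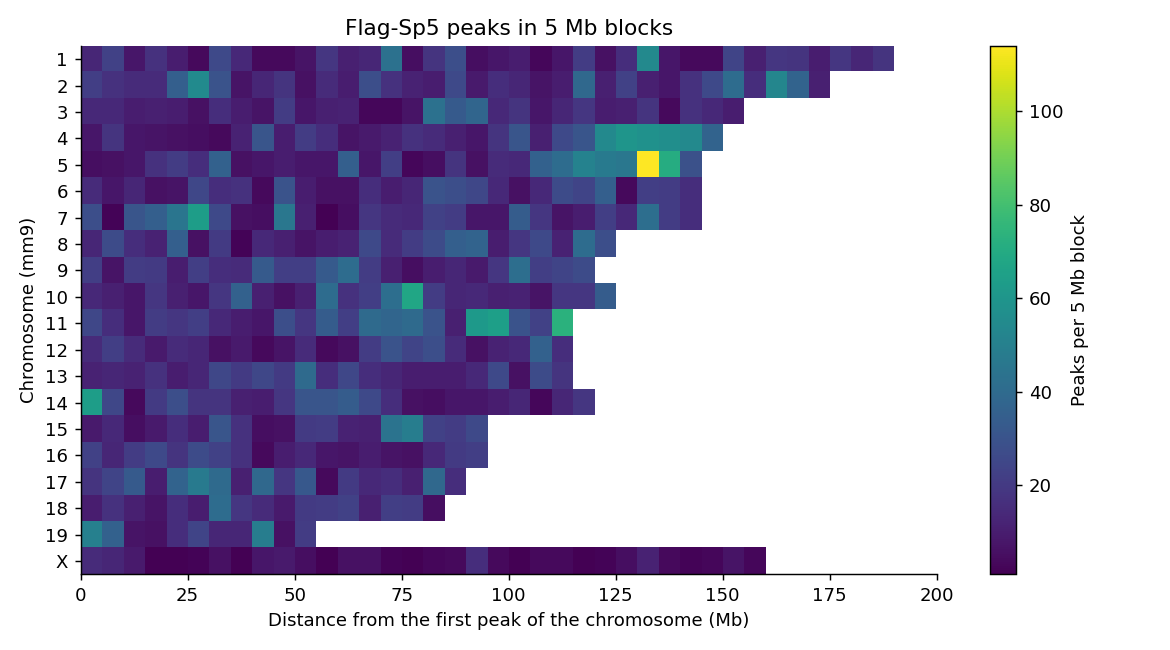
Number of peaks in consecutive 5 Mb blocks, counted from the first peak of each mm9 chromosome (rows), with the colour scale giving peaks per block. The brightest block is on chromosome 5 with 114 peaks, and the X row averages 5.03 peaks per block.

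Flag-Sp5 peaks lay closer together than uniform placement gave. Of the 9428 peaks, 2245 (23.8%) had another peak midpoint within 10 kb, against 716 ± 36.5 (SD over 1000 placements) for the same numbers placed uniformly, a ratio of 3.13 (one-sided permutation test, p = 0.001, the smallest possible). The excess was greatest at the shortest distances. A nearest neighbour within 500 bp was found for 361 peaks, 9.84 times the uniform mean, and one between 500 bp and 1 kb for 358 peaks, 9.67 times the uniform mean. The ratio was 3.00 between 1 and 5 kb and 1.87 between 5 and 10 kb. Against peaks moved by up to 1 Mb, the ratios for these distances were 6.27, 6.20, 1.98 and 1.29. At the other end, 97 peaks stood more than 1 Mb from any other, 3.24 times the uniform mean but 1.19 times the mean of 81.6 ± 7.12 (SD over 1000 draws) when each peak was moved by up to 1 Mb. The share with a neighbour within 10 kb was 31.9% on chromosome 7 and 14.0% on chromosome 18, where uniform placement at their own densities gave 8.07% and 6.31%. On X it was 10.4% (17 of 163 peaks) against 2.04% under uniform placement, a ratio of 5.11 (one-sided permutation test, p = 0.001, the smallest possible). That ratio rests on 17 peaks against a mean of 3.33. Stretches of over 3 Mb without peaks made up 60.9 Mb of the 160.8 Mb span of X, and uniform placement does not keep them. X by itself was not compared with moved peaks, so its ratio does not show closer spacing than on the autosomes.

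With peaks moved by up to 1 Mb, which keeps the broad density, 1061 ± 40.3 peaks (SD over 1000 draws) had a neighbour within 10 kb, and the ratio was 2.12 (permutation test, p = 0.001, the smallest possible). Moves of up to 100 kb, a setting added after seeing the data, lowered the ratio to 1.64.

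**Figure D4:**
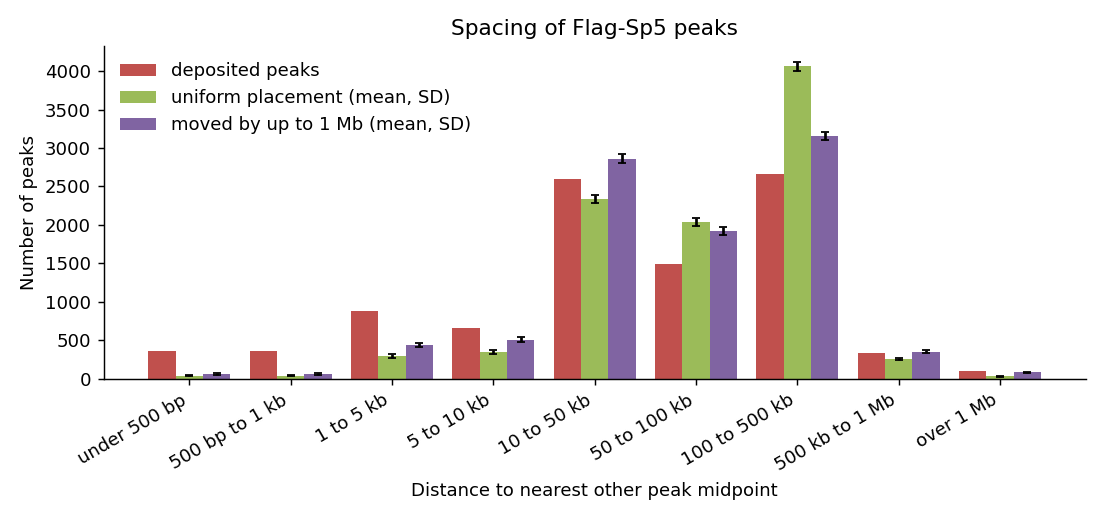
Number of peaks by distance to the nearest other peak midpoint, for the deposited peaks (red), uniform placement (green) and peaks moved by up to 1 Mb (purple); error bars are SD over 1000 draws. The deposited peaks exceed both placements in each bin up to 10 kb, with 361 peaks under 500 bp.

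The region with most peaks within 100 kb was at the start of chromosome 9, where 12 peaks fell between 3000143 and 3031734, a span of 31.6 kb. Chromosome 7 held 11 peaks from 20321045 to 20412368. Regions of 10 peaks each were on chromosome 3 from 89120907 to 89200438, on chromosome 9 from 107529186 to 107612542 and on chromosome 4 from 132514825 to 132612702. The chromosome 9 start region had narrow peaks, with a median width of 156.5 bp, and 2 of its 12 peaks were wider than the median of the list. Median widths in the other regions were 274 bp on chromosome 7, 222.5 bp on chromosome 3, 219.5 bp in the second chromosome 9 region and 240.5 bp on chromosome 4, and 6 or 7 of their peaks were wider than the list median.

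Uniform placement never gave more than 8 peaks in 100 kb in 1000 draws (permutation test, p = 0.001 for 12, 11 and 10 peaks, the smallest possible). Against lists with peaks moved by up to 1 Mb, a comparison added after seeing the data for these windows, the permutation p was 0.004 for a densest window of 12 peaks, 0.021 for 11 and 0.0889 for 10. A single densest window of 10 peaks was thus within what the broad density gave. How often the moved lists held as many separate windows of 10 or more peaks as the deposited list was not tested. This comparison therefore does not settle whether the broad density accounts for the regions of 10 peaks. Among peaks wider than the median the densest window was another one, on chromosome 7 from 28232750 to 28293369 with 7 peaks.

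**Figure D5:**
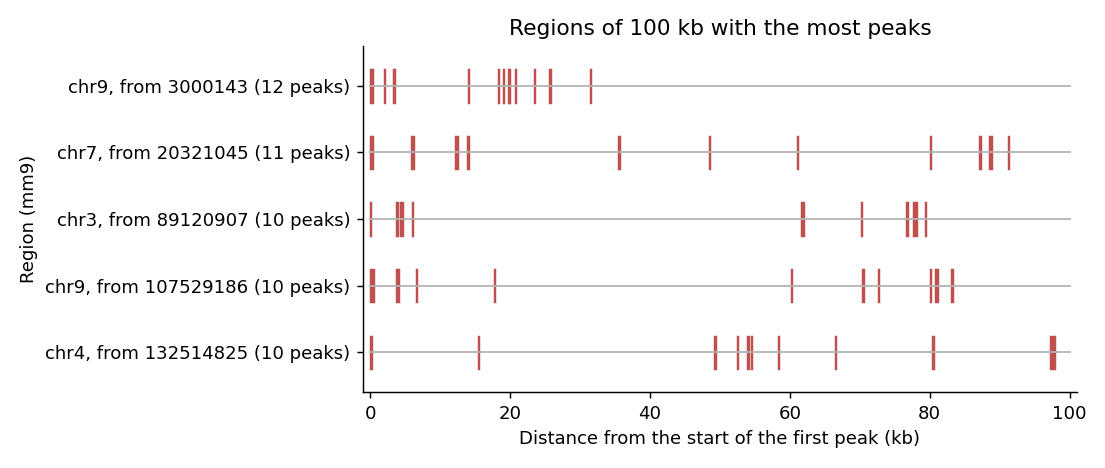
Positions of the peaks (red bars, to scale) in the 5 regions of 100 kb with the most peaks, in kb from the first peak of each region on mm9. The 12 peaks at the start of chromosome 9 fall within 31.6 kb, while the other regions hold 10 or 11 peaks over 79.5 to 97.9 kb.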

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

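For the peak set, the spacing and the chromosomes, the alternatives fixed before the data were examined were, as they applied, merging peaks less than 500 bp apart, keeping peaks wider than the median, distances of 5 and 50 kb, moving peaks by up to 1 Mb, and restriction to autosomes, X and Y; the others, and all those for the densest window, were chosen after seeing the data. Keeping peaks wider than the median leaves 4680 by construction, and merging left 9144. The excess of close neighbours kept its direction and passed the threshold under all 28 alternatives tried. Its ratio was 4.36 within 5 kb, 1.59 within 50 kb, 2.61 after merging, 4.12 for peaks wider than the median, 2.97 for the remaining peaks and 3.13 without the first 100 kb of chromosome 9 that carries peaks. It was 3.13 without X and between 3.07 and 3.27 with each of the 19 autosomes left out. Those 19 lists were compared with 200 placements each and share most peaks with the full list. They show only that no single autosome carried the excess. Apart from the moves of up to 1 Mb and 100 kb, the spacing alternatives used uniform placement, which does not keep the broad density. The ratio of X to autosome density lay between 0.224 and 0.302 under all 7 alternatives, with X the lowest chromosome wherever chromosomes were ranked. The highest count in a window passed the threshold under all 7 alternatives, but the place changed: within 200 kb it was chromosome 3 from 89017837 to 89200438 with 16 peaks, and without the chromosome 9 start region it was the chromosome 7 region of 11 peaks. Restricting the list to autosomes, X and Y removed no peak and so tests nothing. No paired analysis was possible because the list has no value for any single library, and for the same reason no replicate could be left out. The unknown depth and threshold limit what an absent peak can show.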

Other observations

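The comparisons with merged peaks and with peaks moved by up to 1 Mb were fixed before the data were examined, although what the moved peaks would have to show was set down after their value was seen. The comparison of X with the autosomes was also fixed then, but the tests of explanations for its low density, the tests of peak widths and of the chromosome 9 start, and the stretches named here, were chosen after seeing the data. The longest stretch between neighbouring peaks lay on X, from 120517744 to 130208485, and measured 9.69 Mb. Chromosomes 3 and 7 held the next longest, from 69499506 to 76627050 (7.13 Mb) and from 39310767 to 46432572 (7.12 Mb). X accounted for 8 of the 20 longest stretches and for 13 of the 47 above 3 Mb. A chromosome with fewer peaks per Mb has more long stretches even under uniform placement. The number that the density of X alone would give was not worked out. The chromosome 7 region of 11 peaks lay close to a stretch of 4.61 Mb without peaks, from 20472588 to 25084938.

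Peaks with a neighbour within 10 kb were slightly wider than the others, with medians of 203 bp (2245 peaks) and 193 bp (7183 peaks; two-sided permutation test, p = 0.0001, the smallest possible).

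The low density on X was weighed against long empty stretches and against copy number. Leaving every stretch of over 3 Mb without peaks out of all chromosomes raised X to 1.63 peaks per Mb (upper Poisson limit 1.90), still under the lowest autosome at 2.93, which argues against a few long stretches as the whole cause. A lower copy number of X, with weaker signal, may leave fewer peaks above a threshold and narrower ones. X peaks had a median width of 183 bp, below the lowest autosomal median of 185 bp on chromosome 3. Autosomal peaks together had a median of 195 bp, and the difference from X missed the threshold (two-sided permutation test, p = 0.0605). The copy number explanation thus stays open without read counts. Gene content and the share of X open to mapping were not tested.

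The closeness of peaks could come from the splitting of single bound regions by the peak caller or from broad differences in density. After peaks less than 500 bp apart were merged the ratio to uniform placement was 2.61, and against peaks moved by up to 1 Mb it was 2.12, each with a permutation p of 0.001. These values argue against broad density alone, and against splitting across gaps of less than 500 bp alone, as the whole cause. Splitting across wider gaps was not tested, as such peaks were not merged. Uniform placement does not keep the broad density, so the 2.61 includes any effect of it. The peaks that were moved had not been merged, so the 2.12 includes any effect of splitting. Merged peaks were not compared with moved peaks, so both acting together were not tested. Whether close peaks share a promoter or an enhancer was not tested, since no mm9 annotation was used here.

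The 12 peaks at the start of chromosome 9 were 29.6 times the 0.405 peaks that the density of that chromosome gives for 100 kb. An edge effect common to chromosome starts would raise the other 19 chromosomes too, but these held 6 peaks in the same interval against 7.09 expected, a ratio of 0.847 (95% Poisson interval 0.311 to 1.84). That argues against such a shared effect. Repeated sequence at that position could also give such a group of narrow peaks; it was not tested, as the sequence was not used here, so the region should be read with caution. No biological explanation was tested for it.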
